A study of Homo sapiens with 4 samples.

How the data were processed

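Total RNA from MIA PaCa-2 cells, an established human pancreatic carcinoma line, was compared 48 h after transfection with 50 nM of a mimic of the microRNA miR-145 or with a scrambled control RNA. Per the labels, cells were grown in medium with 10% serum and 1% antibiotic mix, and 0.4 µg of RNA entered each labelling. The RNAs were hybridised together, in 2 colours, to Agilent whole-genome arrays of 60-base probes, and 4 scanner files were deposited: 2 with the control RNA in Cy5 (red) and 2 with the miR-145 RNA in Cy5, numbered as replicates 1 and 2 of each dye orientation.

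Per the file headers, spot intensity in both channels was extracted with Agilent Feature Extraction 10.5.1.1, which gives a mean pixel intensity, a local background intensity and a processed intensity that is already background-subtracted, detrended and dye-normalized. The deposited log10 ratio of red over green in each file was made from the processed intensities, per the file headers. Probe coordinates in the files are those of genome build hg18. The authors also deposited 1 table with a log2 fold change, a linear fold (ratio), p-values before and after adjustment, and a moderated t and log-odds score per gene. Per the submitters' processing notes limma was used for it, while its version, background correction, normalization and design are not given in the sources used here. Its direction is not stated either: over 18522 probes its log2 values correlated with the values computed here at r = 0.941, so it was read as miR-145 over control.

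The replicate numbers were checked before any comparison. On 2640 replicate spots of 264 probes, the deviations from the probe mean correlated at 0.934 and 0.898 in red and at 0.846 and 0.883 in green between files of the same array position. Between positions they correlated at 0.542 to 0.556 in red and 0.704 to 0.726 in green. The headers name 1 slide, 2 array positions and 2 scans of each. Replicate 2 was therefore taken as a second scan of the same 2 hybridisations, and nothing in the labels says that the dye-swapped hybridisations used different extracts. The design fixed before the data were examined sets, for this case, 1 replicate of each RNA: scans were averaged, then orientations, with no gene test and no p-value. The SD given beside a value is that of the 2 dye orientations and measures technical error only.

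Values were computed with limma 3.58.1 in R 4.3.3, and figures were drawn with Python 3.11.15. Mean signals were corrected with normexp (offset 50) against the median local background and normalized by loess within each file, with control spots at weight 0, and ratios were turned to miR-145 over control. Spots that the scanner software marked as non-uniform or as population outliers were left out, and spots of a probe were averaged. A probe was kept if it was well above background on every array in either RNA, and the brightest kept probe stood for its gene. Of 41000 probes 24607 were kept. Through a table of current human genes (GRCh38.p14, used for names only) 17460 of them were named by accession, 1374 by symbol and 400 by an older symbol, and 5373 kept the name in the file. This gave 17655 genes. For a gene reported as not well above background in 1 RNA on some or all arrays, a lower bound of the fold was sought. It set the brighter RNA's mean against the dim probe's own value or the lowest value among probes above background, whichever was higher. Both channels were taken after loess and Aquantile scaling. For each such gene reported the dim probe's own value was used, so the fold given is a ratio of channels that hold the offset of 50 and not a bound. That offset draws the ratios of dim probes toward 0.

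A gene counted as lower or higher if its mean log2 ratio was at least 0.5 away from 0 and had the same direction in both orientations, and a stricter count used 1. Each of 23 gene lists was described by the number of its members past 0.5 and by the percentile of its median among 10000 random lists of equal size, drawn from 20 bins of mean intensity (seed 145). The named genes are the 12 largest falls and the 12 largest rises among genes above background in both RNAs with the same direction on every array, the measured members of the list of reported miR-145 targets (of which those of largest size are printed), up to 4 members of each other list with the largest absolute log2 ratio, and 11 genes fixed whatever their value. IFIT1, MX1, STAT2, MYL12B, VIM, CDKN1A, GAPDH, H2AX, the genes named in the red patch and the members of gene families fall outside this rule and were chosen after their values were seen. Some items that the rule names are not reported here. The lists, the named-gene rule, the size rule and the alternatives were set before the data were examined, except those said to be added later. Seed sites were to be sought in 3' untranslated regions, but transcript sequences were not used here. Sites were instead sought in each probe's own 60 bases, a choice made after the reference and a first ranking of heptamers in the probes were seen.

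The steps were tested on simulated data made from these arrays. Of 67 genes changed by 1.5 (log2), 67 passed 0.5, of 67 changed by 0.7, 65 passed, and of 66 changed by 0.3, 0 passed. Of 17349 unchanged genes 1 passed 0.5 and 0 passed 1. The simulated noise came from probes outside the red patch and was drawn separately for each probe. These counts therefore cover neither that patch nor errors that probes share, and are no false-call rate for the real arrays. The planted sizes were ratios that already hold the offset. How much of a true change the offset hides in dim probes was therefore not tested, and the counts do not give the share of true changes found. A list of 30 genes shifted by 0.2 was recovered at 0.18, and 7% of 200 unshifted lists fell outside the central 95% of their random lists. Alternatives covered background correction, normalization, the deposited log ratios and table, the dim-probe filter, the choice of probe, marked spots, each scan, each dye orientation and limma over all 4 files.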

Results

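RNA of MIA PaCa-2 cells transfected with miR-145, a microRNA, was compared with RNA of cells given a scrambled control, 48 h after transfection, to find the transcripts that differ between them. The 4 files hold 2 hybridisations with opposite dyes, each scanned 2 times, so each RNA has 1 replicate. Every file has 45015 spots. Of the spots for genes, 61.0% to 62.5% were well above background in each channel and 0 were saturated. The scans of 1 hybridisation had ratios that correlated at 0.933 and 0.937 over probes above background, and ratios of the opposite orientations at 0.467 to 0.484. Changes are log2 ratios of miR-145 over control, the error is the SD of the 2 dye orientations, and no difference has a biological replicate check. The number of arrays limits the precision.

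The largest falls in miR-145 RNA were in F11R, a junctional adhesion molecule of tight junctions, and PODXL (podocalyxin), a sialomucin of the cell surface. F11R fell by 68.8%, with a log2 ratio of -1.68 ± 0.13, and PODXL fell by 67.1%, with -1.60 ± 0.08. TMEM9B, a lysosomal transmembrane protein, had -1.60 ± 0.24. SWAP70, an actin-binding exchange factor for Rac, fell by 53.4% (-1.10 ± 0.15). The largest rises were in PTX3, a secreted pentraxin of innate immunity, at 2.89-fold (1.53 ± 0.03), and in the transcription factor KLF2, at 2.04-fold (1.03 ± 0.01). Among 17655 genes, 7 were lower and 2 higher by at least 1. Besides those named, the lower ones were ABRACL (-1.11 ± 0.03), the D-aminoacyl-tRNA deacylase DTD1 (-1.09 ± 0.07) and the endoplasmic reticulum protein ERLIN1 (-1.01 ± 0.07).

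At 0.5, 158 genes were lower and 26 higher, and 100 and 14 of them passed 0.5 in each orientation alone. The falls next in size were in SPTLC1, a subunit of the enzyme that starts sphingolipid synthesis (-0.96 ± 0.33), C5orf15 (-0.94 ± 0.00), the Golgi membrane protein GOLM1 (-0.93 ± 0.03), the depalmitoylase ABHD17C (-0.89 ± 0.01) and OGFRL1 (-0.89 ± 0.06). The rises next in size included the aggrecan-cleaving protease ADAMTS4 (0.84 ± 0.11), the chemokine CCL5 (0.77 ± 0.00), the type III collagen chain COL3A1 (0.72 ± 0.04) and the crosslinking enzyme TGM2 (0.72 ± 0.13). SERPINB8, a protease inhibitor, rose by 0.74 ± 0.15, THSD1 by 0.69 ± 0.13, the connexin GJB5 by 0.68 ± 0.01 and FICD, which modifies the chaperone BiP, by 0.66 ± 0.13. The sulfotransferase CHST4 rose by 0.66 ± 0.03 and TGFBR3, a co-receptor for TGF-beta, by 0.63 ± 0.18. The same size rule was applied to the difference between the dye orientations divided by 2, which holds no difference between the RNAs. The rule then called 17 and 2 genes, of which 5 and 2 lay outside a patch of stray red signal described further on. Of the 158 lower genes, 146 lay outside that patch.

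Other probes of some of these genes read differently. SWAP70 had a second kept probe at 0.07, SPTLC1 1 at 0.22, TMEM9B 1 at -0.57, ABHD17C 1 at -0.15 and KLF2 1 at 0.09. Among 70 lower genes with over 1 kept probe, 68 had all probes below 0, and among 10 higher genes 10 had all above 0. The authors' deposited table uses another probe for several genes and gives log2 fold changes of 0.06 for SWAP70, 0.05 for DTD1, 0.29 for SPTLC1, -0.01 for GOLM1, -0.65 for TMEM9B, 0.17 for KLF2, 0.05 for ADAMTS4 and 0.39 for TGM2. The probes that table uses for DTD1, GOLM1 and ADAMTS4 were not among those kept here as above background. The second kept probe of GOLM1 had -0.89. With the scanner's processed signals ABHD17C had -1.55, ADAMTS4 1.38 and CHST4 1.06. The counts depended on the processing: median centring in place of loess gave 95 lower and 51 higher genes, the scanner's processed signals 452 and 227, and the deposited log ratios 442 and 230.

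**Figure D1:**
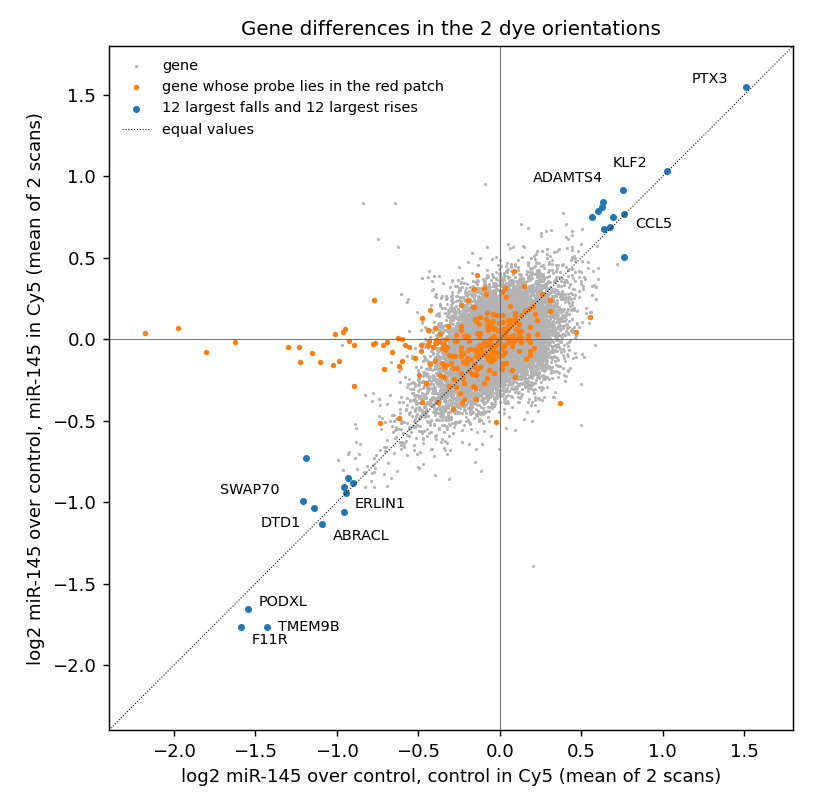
Each point is a gene, with its log2 ratio of miR-145 over control from the hybridisation with control in Cy5 (x axis) and with miR-145 in Cy5 (y axis), each the mean of 2 scans. The 12 largest falls and 12 largest rises have the same sign on both axes, with F11R at -1.59 and -1.77 and PTX3 at 1.51 and 1.55. SPTLC1 lies farther from the line of equal values, at -1.19 and -0.73. Genes of the red patch spread to the left at about 0 on the y axis.

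On hg18 the PODXL probe lies on chromosome 7 from 130835675 to 130835734 (minus strand), and its sequence, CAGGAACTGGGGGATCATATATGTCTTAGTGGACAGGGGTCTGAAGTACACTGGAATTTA, holds ACTGGAA, a 7-base site for the miR-145-5p seed. The kept SWAP70 probe is on chromosome 11 from 9729693 to 9729752, the PTX3 probe on chromosome 3 from 158643663 to 158643722 and the KLF2 probe on chromosome 19 from 16299246 to 16299305, all on the plus strand. Whether these stretches are coding or untranslated was not analysed here.

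Of 56 measured genes reported in the literature as miR-145 targets, 10 were lower, 0 higher and 46 under the size of 0.5, while 13 were lower and 1 higher with the processed signals or the deposited log ratios. The lower ones were F11R, PODXL, SWAP70, GOLM1, the actin-binding LASP1 (-0.84 ± 0.09), the core-binding factor subunit CBFB (-0.77 ± 0.01), the calcineurin catalytic subunit PPP3CA (-0.72 ± 0.05), the Src-family kinase YES1 (-0.62 ± 0.03), the GTPase NRAS (-0.59 ± 0.12) and the sheddase ADAM17 (-0.58 ± 0.10). The next values were -0.47 for SRGAP2, -0.44 for the actin-bundling FSCN1, -0.43 for NUDT1, -0.41 for MAP4K4 and -0.40 for CTNND1, and CLINT1 had -0.22 ± 0.14. Below 0 in both orientations were 37 of the 56, and the list median was -0.10, below all of 10000 random lists (percentile 0). Several reported targets had values near 0 or above it. IRS1 had -0.02 ± 0.02, RREB1 -0.09 ± 0.03, CDK6 -0.10 ± 0.07, MYC 0.21 ± 0.03, IGF1R 0.19 and DFFA 0.18 ± 0.03. In the authors' deposited table MYC had 0.02, from another probe. CCN2 was not well above background in control RNA on any array. Its measured ratio was 1.29-fold higher in miR-145 RNA (log2 0.37, and 0.33 to 1.85 over the alternatives). FLI1 was not well above background in miR-145 RNA. Its ratio with that offset was 1.08-fold higher in control RNA (log2 of miR-145 over control -0.11, and -0.60 to -0.08 over the alternatives). FSCN1 was dim and had -1.71 from the scanner's processed signals and -0.71 in the authors' deposited table. The list median was -0.17 with the processed signals and -0.02 in the deposited table, where 6 of 58 members were lower and 0 higher. F11R and PPP3CA, lower here, have no entry in that table. Whether a member was first picked from these RNAs is not known.

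Probes that hold a miR-145-5p seed site in their own bases were lower as a group. The 312 probes with a site of 7 or 8 bases had a median of -0.05 against 0.00 for 23300 probes with none, below all of 10000 random sets of equal size and intensity. The 69 probes with the 8-base site AACTGGAA had the lowest median, -0.07, the 137 with ACTGGAA had -0.04, the 106 with AACTGGA -0.03 (percentile 3.94, within the central 95%) and the 275 with only ACTGGA -0.03. Among 16382 heptamers ranked by the shift of the probes that hold them, ACTGGAA stood at 1 and AACTGGA at 3 from the lowest, and the reverse complement TTCCAGT at 14002. The 167 probes with a site of at least 7 bases for miR-145-3p, the other strand of the duplex, had a median of 0.01 (percentile 85.6). The difference between site and no site was -0.02 without the dim-probe filter and -0.03 in the orientation with control in Cy5. A probe covers only a small part of its transcript, so probes with no site include genes with one elsewhere.

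**Figure D2:**
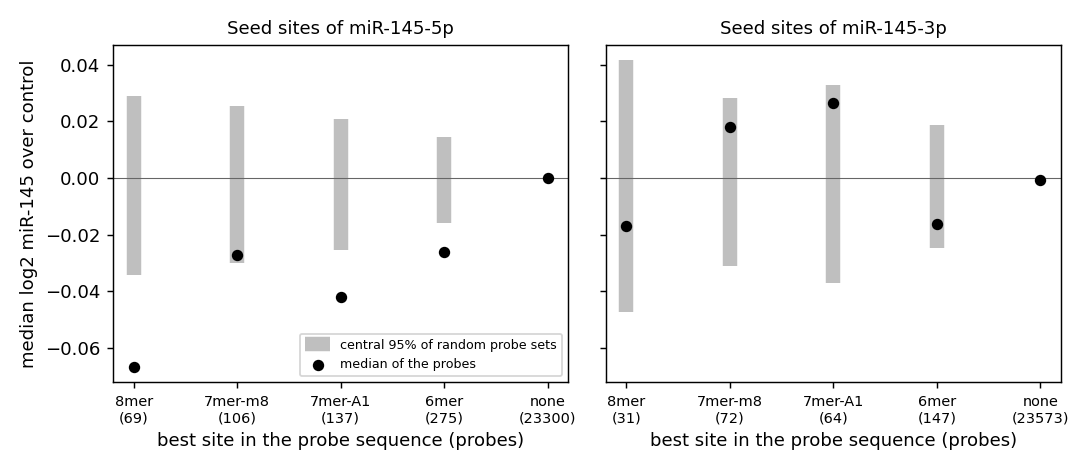
Median log2 ratio of miR-145 over control (y axis) of probes grouped by the best seed site in their sequence (x axis, number of probes), for both strands of the miR-145 duplex, with grey bars for the central 95% of random probe sets. For miR-145-5p the 8-base class lies lowest at -0.07, outside its bar.

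Genes of DNA replication and mitosis were slightly higher in miR-145 RNA as groups, with 0 members at 0.5 or higher. With the processed signals, median centring or the deposited log ratios 2 of the 31 G1/S genes reached it, and 1 of the 32 G2/M genes did with the deposited log ratios. The list of 31 genes of the G1/S transition and DNA replication had a median of 0.21 (percentile 100), and 24 were above 0 in both orientations. Its highest values were in the flap endonuclease FEN1 (0.48 ± 0.16), the ribonucleotide reductase subunit RRM2 (0.44 ± 0.03), cyclin CCNE1 (0.37 ± 0.01) and the replication clamp PCNA (0.33 ± 0.17). The 32 genes of G2/M and mitosis had a median of 0.18 (percentile 100), none was below 0 and 27 were above 0 in both orientations. The kinase AURKB had 0.39 ± 0.13, the topoisomerase TOP2A 0.37 ± 0.07, CDK1 0.37 ± 0.16 and the kinesin KIF23 0.33 ± 0.11. The 24 genes that RAS-MAPK signalling induces had a median of 0.14 (percentile 100), with 0.49 ± 0.11 for EGR1, 0.32 for ETV5, 0.30 for ETV1 and 0.22 for FOS, and 19 of them above 0 in both orientations. Of these genes 0 reached 0.5, against 4 with the processed signals or the deposited log ratios, where FOS had 0.59 and 0.60 and ETV1 0.55 in both.

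The interferon-response list, which covers genes that transfected RNA can induce, had a median of 0.15 over 25 genes (percentile 100), and 16 were above 0 in both orientations while 0 reached 0.5. The antiviral OASL had 0.46 ± 0.03, the ubiquitin-like ISG15 0.33 ± 0.07, the interferon IFNL1 0.33 ± 0.03 (0.90 with the processed signals and 0.91 with the deposited log ratios) and IFIT1 0.30 ± 0.01, whereas MX1 had -0.13 and STAT2 -0.11. RSAD2 was above background in control RNA on only 2 of 4 arrays. Its measured ratio was 1.24-fold higher in miR-145 RNA (log2 0.31, and 0.15 to 1.48 over the alternatives). The list median was 0.08 with no dim-probe filter and 0.09 in the deposited table, and it was 0.21 with the processed signals and 0.22 with the deposited log ratios, where 5 genes reached 0.5 in each. Of 15 NF-kB and cytokine genes, CCL5 was higher, TNFAIP2 was lower (-0.50 ± 0.16) and 13 were under the size, while 2 were lower with the processed signals or the deposited log ratios and 0 with median centring. LTB had -0.36 and CXCL3 -0.29, and the median of -0.04 lay within the random range (percentile 20.5).

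Of 40 genes of the actin cytoskeleton and adhesion, 5 were lower, 2 higher and 33 under the size. With the processed signals or the deposited log ratios 7 were lower, with median centring 3, and with the mean of all kept probes 2. Besides SWAP70 and LASP1, which the target list also holds, the tropomyosin TPM3 (-0.69 ± 0.04), the myosin light chain MYL12B (-0.53 ± 0.05) and ACTB (-0.50 ± 0.66) were lower. ACTB had -0.97 in 1 orientation and -0.03 in the other, and TPM3 had -0.43 as the mean of its 9 probes and 0.01 in the authors' deposited table, from another probe. The light chain MYL9 (0.59 ± 0.02) and VCL (vinculin, 0.51 ± 0.04), a focal adhesion protein, were higher. The list median of -0.05 lay within the random range (percentile 3.29). In each orientation alone it was near 0, at -0.003 with control in Cy5 and 0.013 with miR-145 in Cy5. It lay just below the random range with the spots of the red patch left out (-0.0524). With median centring it was 0.07, within its own random range. Of 13 smooth-muscle genes, VCL was higher and 12 were under the size, with 0.34 for the calponin CNN2, 0.32 for the transcription factor SRF and 0.29 for SMTN. Their median of 0.09 (percentile 99.4) lay above the random range, and inside it with median centring (0.083) and with no dim-probe filter (0.036). It was 0.15 with the processed signals or the deposited log ratios and 0.05 in the deposited table.

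Few epithelial or mesenchymal genes passed 0.5. Of 17 epithelial genes 0 passed 0.5, with 0.41 for the keratin KRT19, -0.17 for PKP3 and a median of 0.04 (percentile 91.3). That median was 0.13 with the processed signals and with the deposited log ratios, above the random range in both. Of 13 mesenchymal genes COL3A1 was higher and 12 were under the size, with 0.20 for both ZEB1 and SNAI2, -0.17 for COL6A1, -0.04 for VIM and a median of 0.02 (percentile 77.6). With the processed signals or the deposited log ratios 3 of them were higher and SNAI2 had 0.75, and 0 were higher in the deposited table. Of 21 TGF-beta genes TGFBR3 was higher and 20 were under the size, while 2 were higher with the processed signals or the deposited log ratios. The receptor TGFBR1 had -0.36 and the inhibitor BAMBI 0.32, and the median was 0.03 (percentile 88.2). Among 23 genes of the insulin-IGF-PI3K pathway 0 passed 0.5, with -0.25 for PIK3CB, -0.17 for TSC1 and a median of -0.03 (percentile 27.6).

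The list of unfolded-protein and amino-acid stress was lower as a group, with a median of -0.12 over 22 genes (percentile 0.08) and 11 below 0 in both orientations. PSAT1, an enzyme of serine synthesis, was lower (-0.84 ± 0.06), and DNAJB9, an endoplasmic reticulum co-chaperone, was higher (0.58 ± 0.28). The transcription factor ATF4 had -0.39 ± 0.17 and TRIB3 -0.27 ± 0.25. The list median was -0.07 with median centring, and 2 members were lower with the processed signals or the deposited log ratios. Of 23 p53 target genes the death receptor TNFRSF10B was lower (-0.71 ± 0.24) and 22 were under the size, with 0.32 for FAS, -0.31 for GDF15, 0.03 for the cell-cycle inhibitor CDKN1A and a median of 0.03 (percentile 84.6). Of 22 apoptosis genes 0 passed 0.5. BIRC2 had -0.29 and BAK1 0.28, and the median was 0.02 (percentile 76.4). With the processed signals or the deposited log ratios 2 p53 target genes were lower and 1 apoptosis gene was higher.

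In the remaining lists few genes passed 0.5. Of 21 genes of cholesterol and lipid synthesis 0 passed, with -0.43 for the desaturase SCD, -0.41 for its regulator SREBF1 and a median of 0.00 (percentile 47.8). Of 19 hypoxia and angiogenesis genes 0 passed, with 0.39 for ADM, -0.30 for NDRG1, -0.22 for VEGFA and a median of 0.01 (percentile 70.2), while 2 were higher with the processed signals or the deposited log ratios. Of 8 mucins and pancreatic cancer surface proteins 0 passed, with -0.44 for MUC20, -0.28 for MUC1 and a median of -0.05 (percentile 12.3), while 1 was lower with the processed signals or the deposited log ratios. Of 16 genes of the microRNA machinery 0 passed, with 0.32 for DICER1, 0.20 for AGO2 and a median of -0.04 (percentile 21.4). Of 15 housekeeping genes ACTB was lower, HPRT1 had -0.28, TFRC 0.20 and GAPDH -0.12. The median was -0.04 (percentile 13.1) but 0.14 with median centring, where 0 were lower. The count of lower genes was also 0 with the processed signals, no background subtraction, the deposited log ratios, the mean of all kept probes and the miR-145-Cy5 orientation.

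Few markers of other cell types were measured, and the list medians lay within the random range. Of 5 measured fibroblast and stellate-cell markers COL3A1 was higher, COL1A2 had -0.07, ACTA2 0.08 and the median was 0.05 (percentile 79.7). Of 4 leukocyte markers 0 passed 0.5, CD68 had 0.20, CD14 0.08 and the median was 0.06 (percentile 89.7). Of the acinar and islet markers 2 were measured, with -0.05 for PPY and 0.07 for CHGA, and their median was 0.01 (percentile 62.5). From the authors' deposited values 10 of these markers had a median of -0.05, below the random range.

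**Figure D3:**
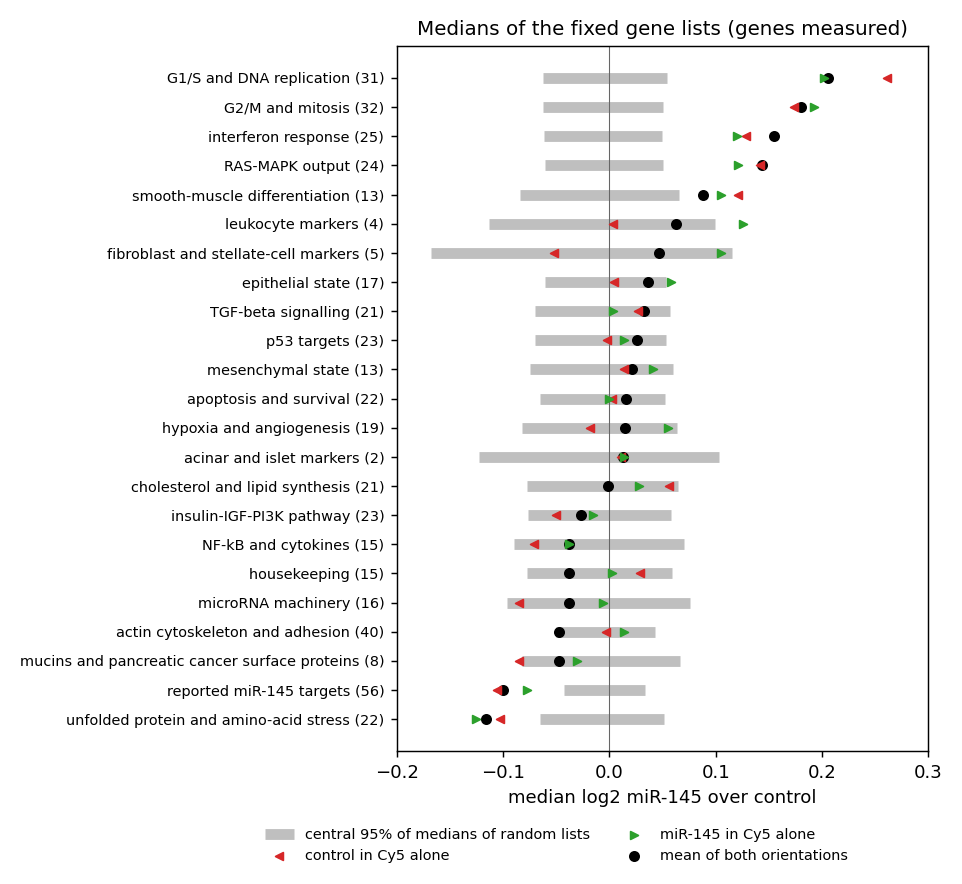
Median log2 ratio of miR-145 over control (x axis) of each fixed gene list (y axis, genes measured), as the mean of both dye orientations (black) and in each alone (triangles), over the central 95% of medians of 10000 random lists (grey). The G1/S list lies farthest right at 0.21 and the unfolded-protein list farthest left at -0.12.

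Some large falls belonged to 1 hybridisation alone and to 1 place on the array. All 41 probes that were at -1 or lower with control in Cy5, and within 0.25 of 0 in the swapped hybridisation, lay in rows 430 to 500 and columns 76 to 85, which hold 1.57% of the probe spots. Their median red signal was 462 on that array and 69.6 on the swapped one, and their green signal 25.8 and 23.5. In the authors' deposited table, 11 of the 20 largest falls lay there, among them the glutamate receptor GRM4 (-2.32), PLEKHG4B (-2.25), the aldo-keto reductase AKR1C4 (-1.65) and MAGEA4 (-1.53). Of the 115 genes at -0.5 or lower with an adjusted p under 0.05 in that table, 30 lay there. At an adjusted p under 0.05 with no size rule, the table has 3066 genes lower and 2976 higher.

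**Figure D4:**
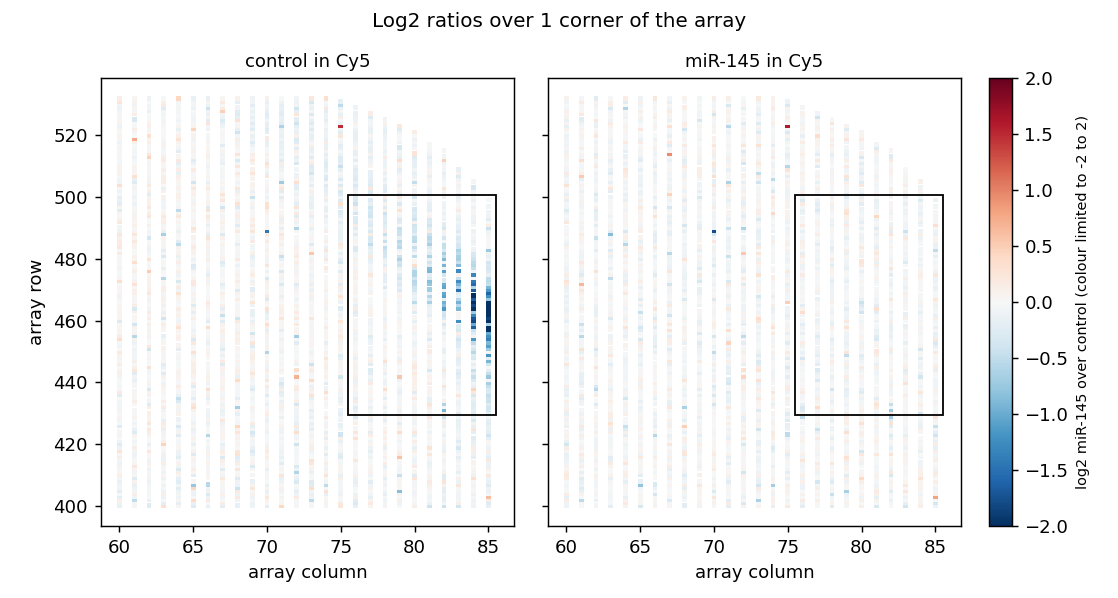
Log2 ratio of miR-145 over control (colour, limited to -2 and 2) of each probe spot by array column and row, over 1 corner of the array, in both hybridisations. The box marks rows 430 to 500 and columns 76 to 85, where low ratios appear with control in Cy5 and not in the swapped hybridisation.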

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

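The tests of the red patch and of a dye effect on the proliferation lists were chosen after the result was seen, and the tests on seed sites in probes and on GC content after the pattern was seen but before the value of the test was.

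A first pattern was a set of probes far lower in miR-145 RNA on the control-Cy5 hybridisation alone. Of these, 100% lay in 1 patch of the array, where red signal was raised and green signal was not. A lower transcript level in the miR-145 RNA would show on the swapped hybridisation too. The 41 patch probes at -1 or lower with control in Cy5, taken whatever their swapped value, had a swapped median of -0.0534. They proved to be the same probes that define the pattern, so this median restates the pattern and is no separate test. For these probes the values argue against a lower level. Red fluorescence spread over that patch is a candidate explanation, found and tested on the same data. Of 281 patch spots whose probes enter no comparison, the median red signal was 80.1 on the control-Cy5 array against 63.7 on the swapped one and 63.4 for such probes outside the patch, a signal outside the main measurement.

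The second pattern was the group shift of probes that hold the miR-145-5p seed site. A dye bias of this heptamer would move the difference between the dye orientations. That difference divided by 2 had a shift of 0.013, in size 16.0% of the shift of the mean (-0.081). Base composition would move other heptamers of the same bases, whose median shift was 0.643% of the shift of the mean. The tables therefore argue against a dye bias and against base composition. A hybridisation bias that stays with 1 RNA in both orientations would not move that difference, so this test cannot decide on it. Action of the mimic through its seed predicts a lower value with a longer site, and the 8-base class was lower than the 6-base class by a difference of -0.0405, while probes with the reverse complement had a mean shift of 0.01. The 7-base class AACTGGA did not follow site length, at -0.0271 against -0.0262 for the 6-base class, and at -0.0153 against -0.0335 with control in Cy5. A direct effect of the mimic remains a hypothesis, and how far it reaches stays open, since sites were sought in probes and not in whole 3' untranslated regions.

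The last pattern was the higher level of the lists of DNA replication and mitosis in miR-145 RNA. Random lists matched on GC content as well as intensity reached at most 0.0538 at the top of their central 95%, below both list medians, and the lowest of the 4 orientation medians was 0.174, so the tables argue against GC content and against a dye effect. With 1 pair of RNAs, a difference between the cultures unrelated to miR-145, such as cell density, cannot be told apart from a response to the mimic. Which of these holds may be decided only with more cultures.

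The results that follow had opposite signs in the 2 dye orientations when each scan was taken alone. These were 11 of 175 results compared, and the difference was not tested. Each value is the log2 ratio with control in Cy5 minus that with miR-145 in Cy5, as the mean over scans. For the medians of lists, taken per scan, it was -0.0666 for epithelial genes, -0.0738 for hypoxia and angiogenesis, -0.188 for fibroblast and stellate-cell markers and -0.150 for leukocyte markers. With scans averaged per gene before the median was taken, the epithelial list (0.0041 and 0.0583) and the leukocyte list (0.0038 and 0.126) were above 0 in both orientations. For single genes it was -0.28 for CD79A, 0.0536 for HDAC2, -0.13 for IRS2, 0.48 for KRT8, -0.27 for RGS5, -0.24 for SOX9 and 0.16 for SRGAP1. KRT8 had 0.39 with control in Cy5 and -0.10 with miR-145 in Cy5.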

How the results depend on the processing

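Leaving out the spots of the red patch and seeking seed sites in probes were chosen after the data were seen, and the other alternatives were planned. Of the medians of the 7 lists outside the random range, 117 of the alternative values kept direction and side and 2 moved inside it, both for the smooth-muscle list: 0.083 with median centring and 0.036 with no filter on dim probes. Of the lists inside the range, 4 alternative values moved outside: epithelial genes at 0.125 with processed signals and 0.129 with the deposited log ratios, the actin list at -0.0524 with the patch left out, and acinar and islet markers at -0.0522 in the authors' deposited table. The seed-site difference kept both in 17 of 17 alternatives, from -0.07 to -0.02. Some alternatives counted here and for the gene families were not separate checks. Aquantile scaling left every ratio as it was, and the limma coefficients of the list and seed values average the same ratios as the main value. No alternative moved the median of all genes by over 0.1. Of the lower and higher genes at 0.5, the scanner's processed signals kept 157 and 26, median centring 92 and 26, the authors' deposited values 76 and 15, the control-Cy5 orientation alone 136 and 17, and the other orientation alone 122 and 23. The deposited values lack some of these genes, F11R and PPP3CA among them. The cause of the moved values was not tested. Limits are set by signal over background, by the choice of probe and by having 1 pair of RNAs.

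Counts at a size of 1 were 7 lower and 2 higher. They were 25 and 20 with processed signals, 24 and 20 with the deposited log ratios, and 158 and 26 at a size of 0.5. The authors' deposited table gave 11 and 1, and of its 11 falls PODXL and ABRACL alone lay outside the red patch. F11R has no entry in that table. No dim-probe filter gave 12 lower, the control-Cy5 orientation alone 18 lower, and the mean of all probes 1 higher. On the control-Cy5 hybridisation, 12 patch probes of kept genes were at -1 or lower. Counts at 0.5 were 158 and 26. They were 452 and 227 with processed signals, 442 and 230 with the deposited log ratios, and 95 and 51 with median centring. Higher genes were 50 with no background subtraction, 41 in the control-Cy5 orientation and 57 in the miR-145-Cy5 orientation. With 1 scan left out in turn, 154 to 161 genes were lower and 25 to 32 higher at 0.5, and 6 to 7 lower and 2 higher at 1. In the authors' deposited table, from other probes, DTD1 (0.0512), SPTLC1 (0.289), SWAP70 (0.0557) and TPM3 (0.0122) had the opposite sign. That DTD1 probe was not among those kept here as above background.

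With the replicate number as a replicate block, limma on all 4 files called 5699 genes lower and 5152 higher at an adjusted p under 0.05 with no size rule, and 5812 and 5267 with the files as separate replicates. At a size of 0.5 as well, both fits called 161 lower and 26 higher, and at 1 8 lower and 2 higher. The numbers mark scans, so these spreads are technical and the counts say nothing of cultures. The block entered as a fixed term, since duplicateCorrelation could not estimate a correlation over 4 files. All files share 1 slide, so a scan block is the same fit. Coding and 5' untranslated sites were not run, since transcripts were not used here.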

Other observations

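The gene families here, and the tests on them, were chosen after the data were seen, and 14 families were compared by symbol. Zinc finger genes (ZNF) lay low as a family in miR-145 RNA: the median of 392 genes was -0.06, below all of 10000 random lists (percentile 0), with 212 below 0 and 55 above 0 in both orientations. ZNF395 (-0.46) and ZNF24 (-0.41) had the lowest values and ZNF367 (0.32) the highest, and no member passed 0.5. The median was below 0 in 15 of 15 alternatives, from -0.11 with the processed signals to -0.02 in the authors' deposited table. Histone genes lay high, with a median of 0.08 over 66 genes (percentile 100), 42 above 0 and 4 below 0 in both orientations, and their median was above 0 in 15 of 15 alternatives. H3C2 (0.35) and H3C4 (0.34), which encode the core histone H3, had the highest values. H2AX, whose symbol lies outside the pattern used for the family, was lower (-0.51). Copies of histone genes are near-identical, so values of single members are uncertain.

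Replication factors (RFC and POL subunits) had a median of 0.12 over 14 genes (percentile 99.7) and mitochondrial ribosomal proteins 0.05 over 79 genes (percentile 99.7), both above 0 in 15 of 15 alternatives. Cytosolic ribosomal proteins had a median of -0.12 with control in Cy5 and 0.11 with miR-145 in Cy5, a dye difference, and their mean of -0.01 turned to 0.20 with median centring.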
